A study of Mus musculus with 12 samples.

How the data were processed

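Brown adipose tissue of 12 mice was profiled on whole-transcript expression arrays, 1 array per mouse. Adipocyte-specific Sel1L knockout mice, made with an Adiponectin-driven Cre recombinase, and floxed littermates without Cre, called controls here, had been fasted for 5 h at room temperature or at 4 °C. Per the labels' protocols, the tissue was snap-frozen, RNA was extracted with Trizol and cleaned on RNeasy columns, and 100 ng of total RNA per sample was converted to biotinylated target. The series' design text speaks of isolated brown adipocytes, whereas the sample labels speak of brown adipose tissue, so RNA of other cell types in the tissue was treated as possible throughout.

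The values used are the log2 expression values of the deposited table, for which RMA is the only tool named, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set on the log2 scale. Its version is not given in the sources used here. The table holds 41345 probe sets with values from 0.27 to 13.02. The scale matches log2 in its range. Values were not centred per gene, and higher means brighter. The medians were 2.06, 2.04 and 2.04 in the control arrays at room temperature, 2.06, 2.09 and 2.04 in the control arrays at 4 °C, 2.05, 2.03 and 2.09 in the knockout arrays at room temperature, and 2.05, 2.05 and 2.03 in the knockout arrays at 4 °C. Raw scanner intensities were not used here, so background and saturation were not assessed per probe. RMA compresses differences of probe sets near the background and near the top of the scale, so that fold changes there are understated. The number of arrays limits the precision.

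Every column of the table was matched to its sample by the sample identifier, with 0 columns left unmapped. Gene names came from the platform annotation. Of the probe sets, 23521 carried exactly 1 gene symbol, 1814 carried several and 16010 were unnamed there. The former represented 22180 genes, of which 1082 had several probe sets. Entrez identifiers of 23328 of them were found in the RefSeq gene table, which changed 0 symbols. Tests were run on the probe sets with 1 symbol, without a filter on brightness. Positions of probes within transcripts were not used here.

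Groups came from the sample titles, with 3 arrays in each of 4 groups. For replicate 3 of the controls at room temperature, the title and the temperature characteristic say room temperature and the source name says 4 °C. It was analysed as room temperature, and the counts with it left out and with it moved to the 4 °C controls are given beside the results. Its readings, given with the cold response of the controls, argue against 4 °C. The titles give a mouse and a replicate number for each array. Nothing further says how the animals were chosen, so p-values measure the spread between these arrays.

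A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with 8 residual degrees of freedom per probe set and a prior of 4.45. The median standard error of a comparison of 2 groups was 0.14 on the log2 scale. Comparisons were knockout against control at room temperature and at 4 °C, 4 °C against room temperature in controls and in knockouts, the difference between the 2 cold responses (the interaction), and the genotype and cold effects averaged over the other factor. P-values were adjusted by the Benjamini-Hochberg method over the 23521 probe sets of a comparison, and an adjusted p under 0.05 was called a change. All adjusted p-values of genes are from limma. Signs are knockout minus control and 4 °C minus room temperature, standard errors are those of the model, and n is 3 arrays per group unless stated.

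The 30 gene lists held 553 entries, of which 501 were measured by a probe set with 1 symbol. They covered Sel1L-Hrd1 ER-associated degradation, ER chaperones and folding, the integrated stress response, the thermogenic program, oxidative phosphorylation, mitochondrial fission and fusion, ER-mitochondria contacts, mitochondrial chaperones and proteases, fatty acid oxidation, lipogenesis, lipolysis and lipid uptake, cholesterol synthesis, glucose uptake and glycolysis, oxidative stress, extracellular matrix, interferon-stimulated genes, immediate early genes, the circadian clock, the cell cycle, adipocyte identity and white adipocyte markers. The others held markers of macrophages, T and B cells, neutrophils and mast cells, endothelium, fibroblasts and preadipocytes, skeletal muscle, Schwann cells and nerve, red blood cells, and sex-linked genes. Members without such a probe set, among them Adrb3 and Cpt1b, were not analysed here, and some items are not reported here. Each list was tested against all other genes with camera in limma, with a preset correlation between genes of 0.01, and the test was repeated with a correlation estimated from the data. That repeat also takes the 8 residual degrees of freedom, so it differs in more than the correlation. For example, the integrated stress response list had an estimated correlation of 0.005. Its unadjusted camera p for genotype at room temperature nevertheless went from 3.46e-18 to 1.69e-05. Adjusted p-values of lists are over the 30 lists of a comparison. The count of members changed was taken from the adjustment over all probe sets and, separately, adjusted over the list alone. The muscle score is the mean log2 value of the 19 skeletal muscle markers of an array.

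The genes named were the 10 largest rises and the 10 largest falls of each comparison of 2 groups among called probe sets whose 3 values in one group did not overlap those in the other, the 5 largest each way for the interaction without that condition, up to 4 called members of each list with the smallest p, or up to 2 given as values where none was called, and a fixed set of genes always reported where measured, among them Sel1l, Syvn1, Os9, Hspa5, Ddit3, Ucp1, Ppargc1a, Dio2, Elovl3 and Fgf21. Predicted genes and genes of microRNA, small nucleolar RNA, olfactory and vomeronasal families were not named. A gene with several probe sets was represented by the one with the highest mean over all arrays. Cross-hybridisation between related genes, such as Scd3 with the other stearoyl-CoA desaturases, was not examined.

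The grouping, tests, lists, the rule for named genes and the alternatives named next were chosen before the data were examined. The alternatives were eBayes with trend and robust settings, leaving out the dimmest 40% of probe sets, testing all 41345 probe sets, cyclic loess or median centring on top of the deposited values, array weights, the replicate number as a block, a fit on only the arrays of the groups compared, leaving out each array in turn, and moving the array with the conflicting label to the 4 °C controls. For lists, the estimated correlation and the mean over a gene's probe sets were also tried. The muscle score as a covariate was added after the data had been seen, as were most of the tests of explanations in the closing section, which names them. Other divisions of the arrays into groups were also tested.

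The procedure was tested on simulated data of 23521 probe sets, with 50 changed by each of 4 known sizes, and the spread of the real arrays. For knockout against control at 4 °C, it recovered 18% of the changes of 0.5 on the log2 scale, 90% of those of 1, and 100% of those of 2 and of 3. For cold in the knockout the shares were 20%, 88%, 100% and 100%, and for the interaction 6%, 60%, 94% and 100%. False calls were 10 of 164, 13 of 167 and 8 of 138 calls. In the simulated comparison without changes, knockout against control at room temperature, 0 genes were called. For lists, a list of 19 genes shifted by 0.5 was called upward, and 0 of 30 unshifted lists were called. The simulated probe sets varied independently of each other. Estimated correlations within the real lists reached 0.308 for ER chaperones, 0.627 for interferon-stimulated genes and 0.934 for skeletal muscle markers. The simulation therefore does not show how often correlated lists are called falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.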

Results

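Expression was measured on 12 arrays of mouse brown adipose tissue, 3 for each combination of genotype and temperature. Sel1L is the adaptor of the Hrd1 ubiquitin ligase in ER-associated degradation (ERAD), the pathway that removes misfolded proteins from the endoplasmic reticulum. The series names thermogenesis, ER-mitochondria contacts and mitochondrial dynamics as its subject, and the design asks what loss of Sel1L in adipocytes changes at room temperature and at 4 °C, and whether it changes the response to cold. Within groups the arrays correlated with a mean Pearson r of 0.987 to 0.992 across probe sets, which are not independent replicates. The first principal component (35.8% of the variance) separated the temperatures, with scores of -37.41 to -12.61 at room temperature and 5.76 to 38.24 at 4 °C. The second (20.8%) separated the arrays labelled knockout, at -28.39 to -11.63, from the controls, at 6.63 to 30.53. Skeletal muscle transcripts varied widely between arrays. The muscle score ranged from 2.62 to 7.89 on the log2 scale and averaged 6.45 in the controls and 4.68 in the arrays labelled knockout. The difference of -1.77 had a 95% interval of -3.81 to 0.27 and an exact two-sided permutation p of 0.09 over 400 permutations of genotype within temperature.

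Sel1l, the deleted gene, read 7.37, 6.96 and 7.23 in the controls at room temperature and 6.18, 6.09 and 5.92 in the arrays labelled knockout, a fall of 2.18-fold (log2 -1.12 ± 0.14 SE, n = 3 per group, adjusted p = 0.00114). At 4 °C it read 6.99, 6.69 and 7.04 in the controls and 6.90, 6.73 and 6.54 in the arrays labelled knockout, and this difference of -0.19 ± 0.14 was not called (adjusted p = 0.605). Within the arrays labelled knockout, Sel1l rose by 0.66 ± 0.14 in the cold (adjusted p = 0.0124), a call lost without knockout replicate 3 at room temperature (adjusted p = 0.0524) or knockout replicate 1 at 4 °C (0.0603). Its interaction was 0.94 ± 0.20 (adjusted p = 0.0862). The Sel1l reading therefore did not check the knockout label at 4 °C. A whole-transcript probe set may read RNA outside the deleted part of the gene, and probe positions were not used here.

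**Figure D1:**
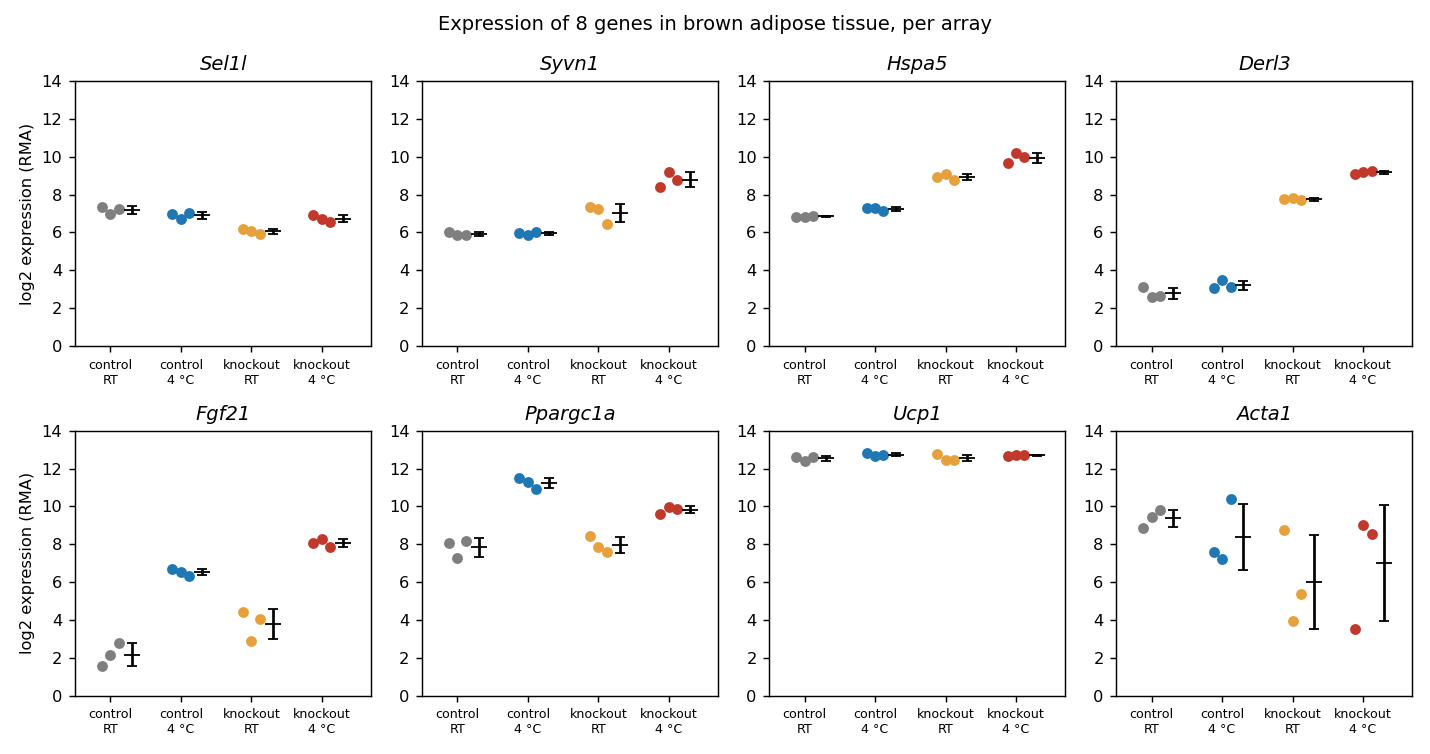
Log2 expression (y axis, 0 to 14) of 8 genes in the 12 arrays, 1 point per array by group, with the mean and SD of each group of 3 as dash and bar. Sel1l averaged 7.19, 6.91, 6.06 and 6.72 in the controls at room temperature and 4 °C and the arrays labelled knockout at room temperature and 4 °C, while Derl3 was at least 4.97 higher in both groups labelled knockout than in the controls of the same temperature, and Acta1 spread from 3.5 to 10.39.

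At room temperature, genes of ER protein folding rose most in the arrays labelled knockout. Sdf2l1, a cofactor of ER chaperones, was 33-fold higher (log2 5.05 ± 0.20 SE, n = 3 per group, adjusted p = 5.31e-08), and Derl3, a derlin of the ERAD machinery, was 31.4-fold higher (4.97 ± 0.15, adjusted p = 5e-09). Hspa5, which encodes the chaperone BiP, rose 4.21-fold (2.07 ± 0.14, adjusted p = 5.25e-06). Ero1a, an oxidase of disulfide bond formation, rose 6.42-fold and Creld2 4.87-fold. Of the 19 measured genes of ER chaperones and folding, 18 rose, 0 fell and 1 was not called (19 rose adjusted over the list alone), with a median of 1.61 and a list adjusted p of 5.47e-56 (camera in limma). Pdia6 (2.20 ± 0.12), Hsp90b1 (2.07 ± 0.13) and Pdia3 (1.57 ± 0.10) were among them. Of 20 measured ERAD genes, 6 rose, Sel1l fell and 13 were not called (9 up and 1 down adjusted over the list alone, list adjusted p = 4.54e-09). Selenos (1.42 ± 0.12) and Edem1 (1.30 ± 0.13) rose, and Os9, a lectin of ERAD, differed by 0.13 ± 0.11 (adjusted p = 0.693). Syvn1, the gene of Hrd1, rose by 1.12 ± 0.23 (adjusted p = 0.0249), a call lost when any of 5 of the 6 arrays was left out (adjusted p up to 0.0906, without knockout replicate 2).

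Targets of the integrated stress response, the PERK and ATF4 arm of the ER stress response, also rose at room temperature, with 8 of 23 up and 0 down (15 up adjusted over the list alone, list adjusted p = 5.18e-17). They included Mthfd2, a mitochondrial folate enzyme, 10.5-fold (3.39 ± 0.29), Psat1 of serine synthesis 4.69-fold (2.23 ± 0.19), the transcription factor Atf5 (1.63 ± 0.11) and Ddit3, which encodes CHOP (1.22 ± 0.14, adjusted p = 0.000555). Fgf21, a secreted metabolic hormone, rose by 1.63 ± 0.35 (adjusted p = 0.034), and lost its call when any of 7 arrays was left out (adjusted p up to 0.129, without knockout replicate 3 at room temperature). This call of Fgf21 was also lost with the muscle score as a covariate. The call of all 3 of these lists held with an estimated correlation (adjusted p = 0.00206, 0.0131 and 0.000508).

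Other large rises were Scd3, a stearoyl-CoA desaturase, 22-fold (4.46 ± 0.26), and Lcn2, a secreted lipocalin, 4.77-fold (2.25 ± 0.36). Derl3, Scd3, Psat1 and Fgf21 averaged 2.78, 1.10, 2.16 and 2.16 in the controls, near or below the array medians of 2.03 to 2.09, so their folds are lower estimates if these readings are background. Genes that fell included Slc7a8, an amino acid transporter, 3.62-fold (-1.86 ± 0.25, adjusted p = 0.00176), Tmem150a (-1.45 ± 0.23), Gys2, a glycogen synthase (-1.23 ± 0.21), and Gdap10 (-1.05 ± 0.15). The calls of Tmem150a and Gys2 were lost with the muscle score as a covariate (adjusted p = 0.0531 and 0.0913), which does not by itself show muscle RNA as the source. Those of Tmem150a (0.11) and Lcn2 (0.0544) were lost with the array with the conflicting label among the 4 °C controls, and that of Lcn2 also when only the 6 arrays compared were fitted (0.0679). Acot1 (-1.63 ± 0.31), Txlnb, Inmt, C1qtnf12, P2rx6 and the rise of Usp18 (2.61 ± 0.50) passed the test but each lost its call without at least 1 array, with adjusted p up to 0.0771, 0.142, 0.158, 0.0722, 0.142 and 0.0824. The calls of Acot1, Txlnb, C1qtnf12 and P2rx6 were also lost with the muscle score as a covariate, and those of Inmt and Usp18 were not.

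Among mitochondrial lists at room temperature, those of oxidative phosphorylation and fatty acid oxidation were called. Of 37 genes of oxidative phosphorylation, 1 fell and 0 rose (9 fell adjusted over the list alone), with a median of -0.15 and a list adjusted p of 4.58e-09, which was 0.0223 with an estimated correlation. Of 20 genes of fatty acid oxidation, Acads (-0.55 ± 0.11) and Hadh (-0.48 ± 0.10) fell and 0 rose (5 down and 1 up adjusted over the list alone), with a list adjusted p of 2.36e-06 (adjusted p = 0.0476 with an estimated correlation). The calls of Acads, Hadh and the complex I gene Ndufa1 (-0.55 ± 0.11) were each lost without several single arrays (adjusted p up to 0.0732, 0.124 and 0.0814) and with the muscle score as a covariate. A lost call shows only that the adjusted p passed 0.05, and does not by itself show muscle RNA as the source. The skeletal muscle markers also lay lower, with 0 of 19 called, a median of -2.30 and a list adjusted p of 4.41e-09 (adjusted p = 0.448 with an estimated correlation). With the muscle score as a covariate and the preset correlation, 1 of 150 list results over the comparisons lost its call, and 3 reversed, all of the muscle markers. At most 1 of the preset-correlation calls of oxidative phosphorylation and fatty acid oxidation given here was therefore lost with this covariate. Their calls with an estimated correlation were not repeated with it, so a share of muscle RNA in those calls was not tested. Of 14 mitochondrial chaperones and proteases, 1 rose and 1 fell (4 and 3 adjusted over the list alone), and the list was not called (list adjusted p = 0.461). The protease Lonp1 rose by 0.66 (SE 0.14, adjusted p = 0.0264), a call lost when any of 5 of the 6 arrays was left out (adjusted p up to 0.101, without control replicate 1) and with the muscle score as a covariate (0.209). The protease Spg7 fell by 0.81 on the log2 scale (SE 0.14, adjusted p = 0.00761), a call lost with the muscle score as a covariate (adjusted p = 0.0692) and with the array with the conflicting label among the 4 °C controls (0.083). For Lonp1 and Spg7 too, a lost call does not by itself show a smaller change or muscle RNA as the source. The thermogenic program was not called, with 0 of 20 genes past the test (1 up adjusted over the list alone, list adjusted p = 0.319). Its members Ucp1, the uncoupling protein (0.04 ± 0.11, adjusted p = 0.942), Ppargc1a (0.14 ± 0.25, 0.896), Dio2 (0.71 ± 0.35, 0.411) and Elovl3 (0.88 ± 0.22, 0.0669) did not pass.

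Cholesterol synthesis had 4 of 16 genes up and 0 down (5 up and 1 down adjusted over the list alone), with Sqle (1.52 ± 0.23) and Lss (1.01 ± 0.16) as examples. Its list adjusted p was 0.000681 (adjusted p = 0.4 with an estimated correlation). The call of Sqle was lost when only the 6 arrays compared were fitted (adjusted p = 0.0558), and those of Lss and Mt2, an oxidative stress gene, with the array with the conflicting label among the 4 °C controls (0.143 and 0.316). Among interferon-stimulated genes only Usp18 passed over all genes, whereas 15 of 17 rose adjusted over the list alone, with a median of 0.98 and a list adjusted p of 1.24e-14 (adjusted p = 0.159 with an estimated correlation). The lists of oxidative stress (1 of 14 up, Mt2 by 0.76 ± 0.13, median 0.13), the circadian clock (0 of 15 called, median -0.21), neutrophils and mast cells (0 of 12 called, median 0.24) and endothelium (0 of 14 called, median -0.28) had list adjusted p-values of 0.0456, 0.0245, 0.0456 and 0.00358. All 4 were lost with an estimated correlation (adjusted p = 0.467, 0.368, 0.467 and 0.4). Each was also lost when at least 1 single array was left out (list adjusted p up to 0.189 without knockout replicate 1, 0.146 and 0.492 without knockout replicate 3, and 0.162 without control replicate 3). Adjusted over the list alone they had 1, 0, 1 and 0 members up and 0, 1, 0 and 1 down.

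In total, limma called 404 of 23521 probe sets at room temperature, 303 higher and 101 lower in the arrays labelled knockout, and 156 by at least 2-fold. The count was 255 without control replicate 2 and 288 without control replicate 3, whose temperature labels conflict. It was 177 (157 higher and 20 lower) with that array among the 4 °C controls, 245 (203 and 42) when only the 6 arrays compared were fitted, and 188 (163 and 25) with the muscle score as a covariate. The lower calls numbered 59, 52 and 58 without control replicates 1, 2 and 3, 61 and 44 without knockout replicates 1 and 3, and 58 over all probe sets with or without a symbol.

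At 4 °C, where the Sel1l reading does not check the label, ER genes were also higher in the arrays labelled knockout. Derl3 was 62.6-fold (5.97 ± 0.15, n = 3 per group, adjusted p = 5.27e-10) and Sdf2l1 59.6-fold higher (5.90 ± 0.20, adjusted p = 7.85e-09). Hspa5 was 6.53-fold higher (2.71 ± 0.14, adjusted p = 1.9e-07) and Creld2 20.1-fold (4.33 ± 0.24). All 19 measured genes of ER chaperones and folding rose, also when adjusted over the list alone, with a median of 2.71 and a list adjusted p of 2.48e-57 (0.00223 with an estimated correlation). Among them were Pdia6 (2.95 ± 0.12), Pdia3 (2.39 ± 0.10) and Sec24d of the coat of ER export vesicles (2.78 ± 0.13). Of 20 ERAD genes 10 rose and 0 fell (14 up adjusted over the list alone, list adjusted p = 1.57e-16, and 0.00223 with an estimated correlation). Syvn1 rose 7.14-fold (2.84 ± 0.23, adjusted p = 5.98e-06), Selenos 4.81-fold, Edem1 4.23-fold and Os9 2.07-fold (1.05 ± 0.11).

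The integrated stress response list had 12 of 23 genes up and 1 down at 4 °C (13 up and 1 down adjusted over the list alone), with a list adjusted p of 2.54e-07 (0.0039 with an estimated correlation). Psat1 (2.79 ± 0.19), the amino acid transporter Slc7a5 (1.85 ± 0.20), Wars (1.43 ± 0.17) and Ddit3 (1.36 ± 0.14) rose. Atf3, a member of this list and of the immediate early genes, fell by 1.36 on the log2 scale (SE 0.28, adjusted p = 0.0126). This call was lost without control replicate 1 (adjusted p = 0.0577) or knockout replicates 2 (0.0549) or 3 (0.0633) at 4 °C. Fgf21 was 2.92-fold higher (1.55 ± 0.35, adjusted p = 0.0197), with its call lost when any of 5 arrays was left out (adjusted p up to 0.0816, without knockout replicate 2 at 4 °C).

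Genes of the thermogenic program were lower at 4 °C in the arrays labelled knockout, with 7 of 20 down and 0 up (9 down adjusted over the list alone). Ppargc1a, the coactivator of mitochondrial biogenesis, was 2.68-fold lower (-1.42 ± 0.25, adjusted p = 0.00473). The lipid-sensing receptor Ppara (-1.49 ± 0.18, adjusted p = 0.000165), Ucp3 (-1.47 ± 0.27) and the estrogen-related receptor Esrrg (-0.82 ± 0.15) fell as well. The list adjusted p was 5.19e-06 (adjusted p = 0.13 with an estimated correlation). Ucp1 (-0.04 ± 0.11, adjusted p = 0.937), Dio2 (0.02 ± 0.35, 0.989) and Elovl3 (-0.19 ± 0.22, 0.759) were not called. The interaction of Ppargc1a, -1.56 ± 0.36, did not pass the test (adjusted p = 0.106), whereas that of Ppara did, as given further on.

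Lipogenic genes followed, with 5 of 19 down and 0 up (10 down adjusted over the list alone). Acacb, an acetyl-CoA carboxylase, fell by 1.18 on the log2 scale (SE 0.12, adjusted p = 3.73e-05), and Gpam, which starts glycerolipid synthesis, by 1.05 (SE 0.14). Fatty acid synthase, Fasn, was 4.72-fold lower (-2.24 ± 0.52, adjusted p = 0.0245), and the citrate carrier Slc25a1 fell (-1.48 ± 0.35, 0.0278). Both calls were lost without some single arrays (adjusted p up to 0.0995 and 0.112, each without knockout replicate 1 at 4 °C). The list adjusted p was 2.12e-05 (adjusted p = 0.415 with an estimated correlation). Of 16 glycolytic genes, 1 rose and 3 fell (1 and 7 adjusted over the list alone), among them Pfkfb3 (-0.92 ± 0.18), with a list adjusted p of 0.00627 (adjusted p = 0.485 with an estimated correlation). Of 16 genes of cholesterol synthesis, 7 rose and Pmvk fell (8 and 1 adjusted over the list alone), with Lss at 2.03 ± 0.16 and Fdps at 1.25 ± 0.20. That list had an adjusted p of 0.000269 (adjusted p = 0.357 with an estimated correlation). Oxidative stress genes had 3 of 14 up and 0 down (4 up adjusted over the list alone), namely Gclc of glutathione synthesis (1.28 ± 0.13), the cystine transporter Slc7a11 (1.33 ± 0.23) and Srxn1 (0.78 ± 0.12). Their list adjusted p was 0.00867 (adjusted p = 0.357 with an estimated correlation), and 0.0915 without control replicate 2 at 4 °C.

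Among mitochondrial lists at 4 °C, oxidative phosphorylation had 2 of 37 genes down and 0 up (3 down adjusted over the list alone), namely Ndufa1 (-0.74 ± 0.11, adjusted p = 0.000813) and Ndufb3, with a list adjusted p of 0.000799 (adjusted p = 0.173 with an estimated correlation). Fatty acid oxidation had 1 of 20 up, the thioesterase Acot2 (0.70 ± 0.12), and 2 down (10 down and 1 up adjusted over the list alone), with a list adjusted p of 5.93e-05 (adjusted p = 0.115 with an estimated correlation). The calls of Ndufb3, Acads and Hadha were lost without some single arrays (adjusted p up to 0.0896, 0.111 and 0.124). Those of Acads and Hadha were also lost with the muscle score as a covariate, and that of Ndufb3 was not. Skeletal muscle markers lay lower here too, with 0 of 19 called, a median of -1.07 and a list adjusted p of 0.0452 (adjusted p = 0.756 with an estimated correlation). Their median was -0.09 without control replicate 3 and 0.14 without knockout replicate 1 at 4 °C, which ended the call (list adjusted p = 0.978 and 0.736), as did leaving out control replicates 1 (0.0525) or 2 (0.0529) or knockout replicate 3 (0.0565) at room temperature. Of the mitochondrial chaperones and proteases, 1 of 14 rose, Lonp1 (0.73, SE 0.14, adjusted p = 0.006), and Hspd1 (-0.51 ± 0.12, 0.0293) and Phb2 (-0.46 ± 0.12, 0.0469) fell (2 up and 4 down adjusted over the list alone, list adjusted p = 0.418). The calls of Hspd1 and Phb2 were lost without some single arrays (adjusted p up to 0.118 and 0.178). That of Phb2 was also lost with the muscle score as a covariate, and that of Hspd1 was not. The list of ER-mitochondria contacts was not called (list adjusted p = 0.187), and 5 of its 24 genes rose and 2 fell (5 and 3 adjusted over the list alone). Its risen members Ero1a (3.74 ± 0.27) and Rrbp1, a ribosome receptor of the rough ER (1.51 ± 0.13), also belong to ER protein synthesis and folding. Acsl4 rose by 0.73 ± 0.13, and Ptdss2, a phosphatidylserine synthase, fell by 1.25 on the log2 scale (SE 0.14). The fission and fusion list was not called either (list adjusted p = 0.187), and of its 19 genes only Mtfp1, a fission factor, changed (-0.75 ± 0.12, adjusted p = 0.00232), with 1 up and 1 down adjusted over the list alone.

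Further large rises at 4 °C were Prr32 (21.2-fold), Fkbp11, an ER prolyl isomerase (14.6-fold), Plscr2 (12.1-fold), Rbm15b (11.2-fold) and Prdm15 (10.4-fold). Rbm15b ends at position 106887075 of chromosome 9, and the ER stress gene Manf starts at 106888753. Signal from this neighbouring gene was not examined. Further large falls were Plk3, a stress-responsive kinase (6.29-fold), Ttpa, the tocopherol transfer protein (6.23-fold), Acot1 (4.83-fold), Gys2 (3.97-fold), the heat shock gene Hspa4l (3.68-fold) and Mavs, an adaptor of RNA sensing (3.63-fold). The controls averaged 1.52 for Prr32, 2.27 for Fkbp11, 2.72 for Plscr2 and 2.35 for Prdm15, again near or below the array medians, so that these folds too are lower estimates if the readings are background. Falls of Lrrc52, Ffar4 and Acsl5 were called but lost without some single arrays (adjusted p up to 0.104, 0.0896 and 0.105). The adipocyte regulator Pparg fell (-0.78 ± 0.17, adjusted p = 0.0144), a call likewise lost when any of 3 arrays was left out (adjusted p up to 0.0689). In total 1365 of 23521 probe sets were called at 4 °C, 850 higher and 515 lower, and 444 by at least 2-fold. The count was 846 (614 higher and 232 lower) without control replicate 1, 842 (612 and 230) without knockout replicate 2, 857 (602 and 255) without knockout replicate 3 and 952 (640 and 312) without knockout replicate 1, all at 4 °C, and 1278 without the array with the conflicting label. With that array among the 4 °C controls the count was 1117 (736 higher and 381 lower). In that fit Ppargc1a, Plk3, Ttpa, Hspa4l, Atf3, Pmvk and Fgf21 were not called (adjusted p = 0.709, 0.378, 0.154, 0.0864, 0.892, 0.363 and 0.102).

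The genotype effects at both temperatures overlapped. Their group means share no array, but their calls share 1 estimate of the spread, so the called lists are not fully independent. Of the probe sets called, 248 rose at both temperatures, where 10.9 would overlap by chance between independent lists, 27 fell at both (2.21 by chance), and 2 changed in opposite directions. The 248 and 27 were 140 and 9 with the muscle score as a covariate, and 148 and 6 with the array with the conflicting label among the 4 °C controls. When only the arrays compared were fitted, with no shared spread, these counts were 167 and 10. The 27 was also 15, 17 and 15 without control replicates 1, 2 and 3 and 13 without knockout replicate 3, all at room temperature, and 49 with trend and robust settings. Across all probe sets, which are not independent replicates, the effects correlated with r = 0.496. The genotype effect averaged over temperatures, which includes the 4 °C arrays whose label Sel1l does not check, was called for 1638 probe sets, 997 higher and 641 lower. The count was 1010 (694 and 316) with the muscle score as a covariate, 1360 without the array with the conflicting label, and 1199 with that array among the 4 °C controls. With the larger number of arrays in this average, 8 of 37 genes of oxidative phosphorylation and 5 of 20 of fatty acid oxidation fell, with 0 and 1 up (14 and 15 down, 0 and 1 up, adjusted over the list alone). The list adjusted p-values were 1.03e-07 and 1.34e-07, and both were 0.0273 with an estimated correlation. The muscle markers had a median of -1.65 in the same comparison.

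**Figure D2:**
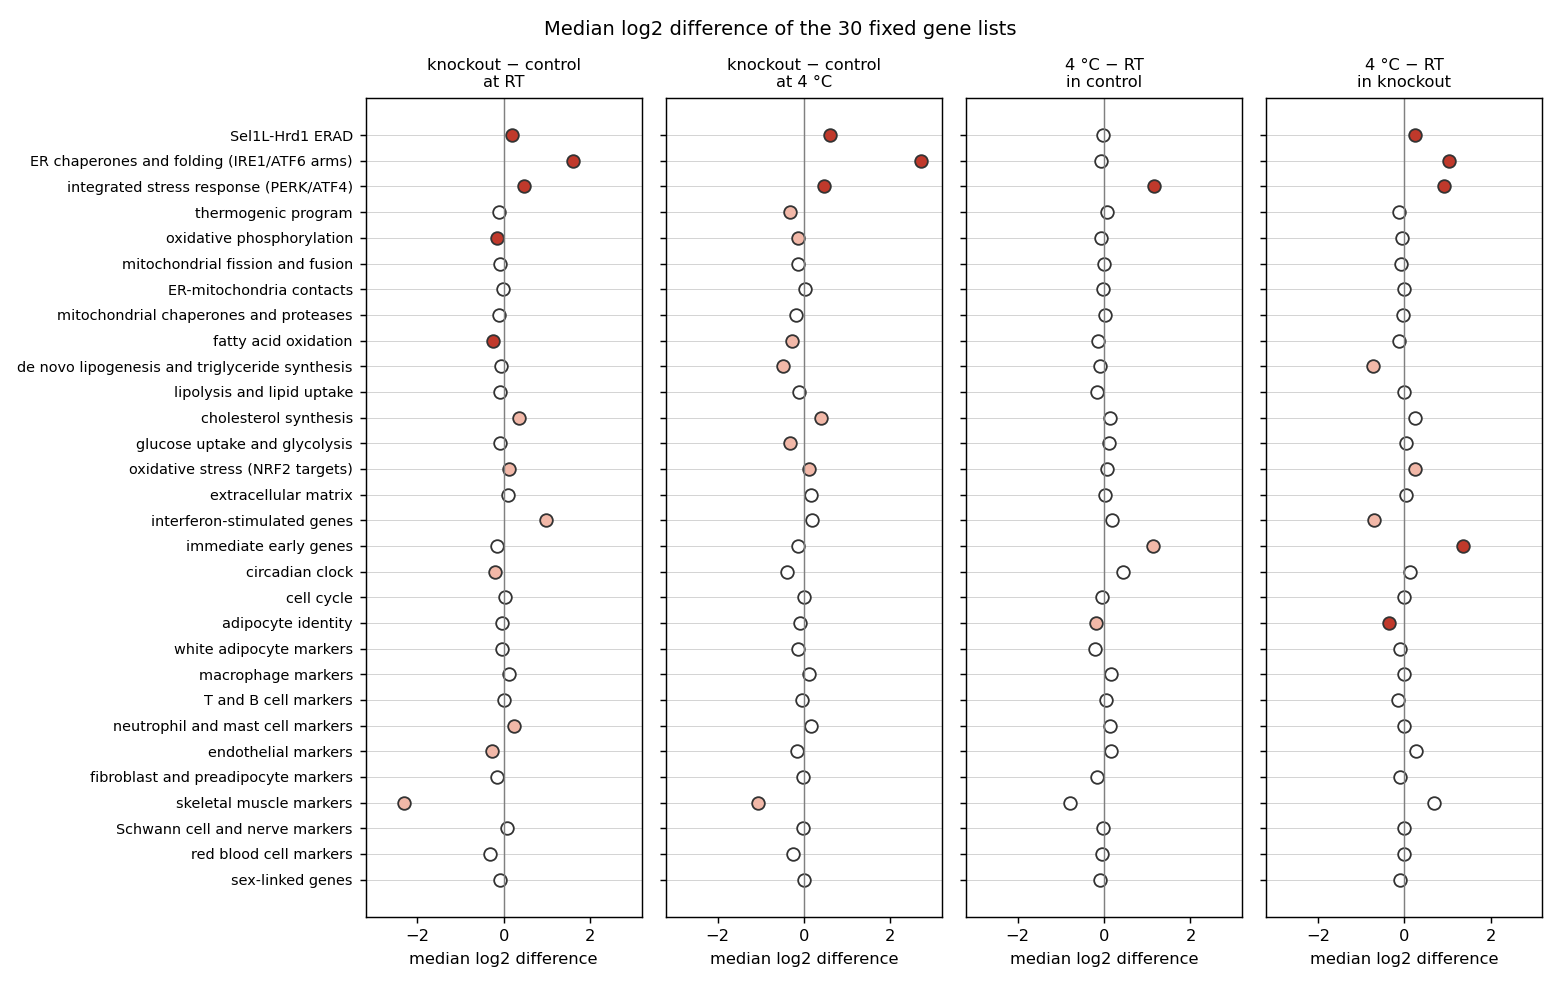
Median log2 difference (x axis) of the measured members of the 30 gene lists (y axis) in the 4 comparisons of 2 groups. Dark red points had a list adjusted p under 0.05 with a preset and an estimated correlation, pale points with the preset one only, and white points with neither, and the ER chaperone list lies at 1.61 and 2.71 for genotype at room temperature and 4 °C.

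Cold changed the controls strongly. Fgf21 rose 20.4-fold from room temperature to 4 °C (4.35 ± 0.35, n = 3 per group, adjusted p = 3.1e-05), Ppargc1a 10.6-fold (3.41 ± 0.25, adjusted p = 2.09e-05), and Dio2, the deiodinase that activates thyroid hormone, 6.6-fold (2.72 ± 0.35, adjusted p = 0.000503). Elovl3, a fatty acid elongase of brown fat, rose 3.55-fold (1.83 ± 0.22). Fgf21 read 1.57, 2.13 and 2.79 in the room temperature controls, close to the array medians of 2.04 to 2.06, so its fold is a lower estimate if these readings are background. Ucp1 read 12.38 to 12.83 over the 12 arrays, close to the top of the scale at 13.02, and its difference of 0.21 ± 0.11 was not called (adjusted p = 0.309). The thermogenic program had 4 of 20 genes up and 3 down (6 and 3 adjusted over the list alone), with the brown adipocyte factor Ebf2 down (-1.31 ± 0.16). As a list it was not called (list adjusted p = 0.406). Of the integrated stress response, 15 of 23 genes rose and 0 fell (17 up adjusted over the list alone), with a list adjusted p of 3.65e-16 (0.000575 with an estimated correlation). Atf3 rose 13.3-fold (3.73 ± 0.28), the amino acid transporter subunit Slc3a2 3.08-fold and Atf5 2.32-fold. Immediate early genes, the first transcripts to follow a stimulus, had 10 of 18 up and 0 down (14 up adjusted over the list alone). Among them were Fosb (14.6-fold, 3.87 ± 0.32), Nr4a3 (9.79-fold, 3.29 ± 0.17) and Klf4 (2.12 ± 0.20), with a list adjusted p of 1.35e-12 (adjusted p = 0.158 with an estimated correlation). Fosb read 1.56, 1.87 and 1.97 at room temperature, below the array medians, and the same limit applies to its fold.

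ER folding genes moved in both directions in the cold controls. Of the 19 in the list 3 rose and 1 fell (4 and 3 adjusted over the list alone), with Dnajb9 up (1.18 ± 0.18), Hspa5 not called (0.41 ± 0.14, adjusted p = 0.0808) and a list adjusted p of 0.734. The median of this list was -0.06, its mean 0.05 and the direction of its test upward. Of 20 ERAD genes, 2 rose and 3 fell (5 and 3 adjusted over the list alone), with Nploc4 (0.68 ± 0.11), Os9 (-0.51 ± 0.11) and Edem1 (-0.58 ± 0.13) as examples and a list adjusted p of 0.976. The call of Edem1 was lost without control replicate 2 at 4 °C (adjusted p = 0.0552). The ERAD median of -0.02 and mean of -0.03 had a sign opposite to that of its test. Among the largest falls were the vessel growth factor Angpt1 (8.57-fold, -3.10 ± 0.27), the insulin receptor substrate Irs3 (6.01-fold), Cebpa, a transcription factor of adipocyte differentiation (5.83-fold, -2.54 ± 0.18), Ano1 (5.64-fold), Tspan18 (5.27-fold), the apelin receptor Aplnr and the lactate receptor Hcar1 (both 4.51-fold). Angpt1, Irs3, Aplnr and Hcar1 averaged 2.62, 2.37, 2.04 and 2.55 at 4 °C, near the array medians, so their folds are lower estimates if these readings are background. Adipocyte identity genes had 4 of 13 down and 0 up (6 down and 1 up adjusted over the list alone), with Lipe (-0.53 ± 0.11) and Pck1 (-0.53 ± 0.11) as further examples. The list adjusted p was 0.043 (adjusted p = 0.41 with an estimated correlation), and 0.0573 with the replicate block. Several single arrays left out also ended this call, with a list adjusted p of 0.0796 without the control array with the conflicting label.

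Of 19 genes of lipogenesis, 2 rose and 4 fell in the cold controls (2 and 4 adjusted over the list alone), and the list was not called (list adjusted p = 0.514). Srebf1 (-1.68 ± 0.22) and Dgat2 (-2.08 ± 0.35) fell and Gpam rose (0.81 ± 0.14). Of lipolysis and lipid uptake, G0s2, an inhibitor of lipolysis (-1.13 ± 0.12), Slc27a1 (-1.30 ± 0.26) and Lipe fell and 0 of 16 rose (5 down and 2 up adjusted over the list alone, list adjusted p = 0.406). Of glucose uptake and glycolysis, 5 of 16 rose and 1 fell (5 and 1 adjusted over the list alone), at a list adjusted p of 0.0549. Pfkp (1.59 ± 0.19), the glucose transporter Slc2a1 (1.12 ± 0.18) and Hk2 (1.12 ± 0.19) rose and Pfkfb3 fell (-1.03 ± 0.18). Oxidative stress genes had 4 of 14 up and 0 down (5 up and 1 down adjusted over the list alone), led by Hmox1 (5.01-fold) and Mt2 (2-fold), also at a list adjusted p of 0.0549. Cholesterol synthesis had 4 of 16 up and 3 down (5 and 4 adjusted over the list alone), with Pmvk up (1.07 ± 0.13) and Hmgcs1 down (-0.78 ± 0.14), at a list adjusted p of 0.525. Clock genes went both ways, 4 of 15 up and 3 down (8 and 4 adjusted over the list alone), with Arntl up (2.34 ± 0.41) and Per3 down (-2.03 ± 0.21), at a list adjusted p of 0.47. The list test asks for a shared direction, so this value does not speak against a change of clock genes in both directions. Endothelial genes had 4 of 14 up and 2 down (4 and 4 adjusted over the list alone), with Sox17 up (1.60 ± 0.23) and Emcn down (-1.05 ± 0.15), at a list adjusted p of 0.55. Matrix genes had 4 of 20 up, among them Col4a1 (1.46 ± 0.24), and 0 down (4 and 0 adjusted over the list alone, list adjusted p = 0.47).

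In total 2606 probe sets were called for cold in the controls, 1140 higher and 1466 lower, and 686 by at least 2-fold. The count was 1733 without control replicate 1 at room temperature, 1718 and 1608 without control replicates 1 and 2 at 4 °C, and 2139 without the array with the conflicting label. With that array placed among the 4 °C controls, as its source name says, limma called 0 probe sets, and 3602 had an unadjusted p under 0.05. That array correlated best with control replicate 1 at room temperature (r = 0.992 across probe sets). It read 2.79 for Fgf21, where the 4 °C controls read 6.35 to 6.67, and 8.17 for Ppargc1a, where they read 10.94 to 11.49. Its score on the first principal component, over all genes, was -29.9. The other room temperature controls scored -37.41 and -36.07, and the 4 °C controls 5.76 to 26.27. These values argue against the 4 °C of its source name, so calls lost with it among the 4 °C controls do not by themselves show an unstable result. The muscle markers had a median of -0.79 for cold in the controls, with 0 of 19 called and a list adjusted p of 0.406.

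The Sel1l reading does not check the label of the knockout arrays at 4 °C. In the arrays labelled knockout, cold raised Fgf21 19.3-fold (4.27 ± 0.35, n = 3 per group, adjusted p = 3.24e-05), Ppargc1a 3.62-fold (1.86 ± 0.25, adjusted p = 0.00082) and Dio2 4.08-fold (2.03 ± 0.35, adjusted p = 0.00305). Elovl3 (0.75 ± 0.22, adjusted p = 0.0501) and Ucp1 (0.14 ± 0.11, 0.587) were not called. The interactions of Dio2 (-0.70 ± 0.49, adjusted p = 0.715) and Elovl3 (-1.07 ± 0.31, 0.216) did not pass the test. That of Fgf21 (-0.08 ± 0.49, 0.98) did not either, and does not show equal responses, since Fgf21 averaged 2.16, near the array medians, in the room temperature controls and 3.79 in the arrays labelled knockout. The thermogenic program had 3 of 20 up and 6 down (5 and 7 adjusted over the list alone), with Irf4, a cold-induced factor of brown fat, up (2.81 ± 0.39) and Ppara (-1.91 ± 0.18) and Esrrg (-1.53 ± 0.15) down. As a list it was not called (list adjusted p = 0.422), with a median of -0.12, a mean of 0.04 and a downward test.

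ER folding genes rose further in the cold in these arrays, with 15 of 19 up and 0 down (16 up adjusted over the list alone), a median of 1.04 and a list adjusted p of 3.83e-21 (0.0316 with an estimated correlation). Hspa5 rose 2.05-fold (1.04 ± 0.14, adjusted p = 0.000643), Sec24d 3.22-fold, Dnajb11 2.56-fold and Manf, a secreted ER stress factor, 2.55-fold. Of 20 ERAD genes 7 rose and 0 fell (10 up adjusted over the list alone), with a list adjusted p of 2.34e-07 (0.0316 with an estimated correlation). Syvn1 rose 3.37-fold (1.75 ± 0.23, adjusted p = 0.000591), Derl3 2.68-fold, Herpud1 2.44-fold and Selenos 2.25-fold. The integrated stress response had 13 of 23 up and 0 down (17 up and 1 down adjusted over the list alone, list adjusted p = 2.7e-13, and 0.00134 with an estimated correlation). Ppp1r15a, a phosphatase subunit that ends this response, rose 4.82-fold and Slc7a5 4.34-fold. Immediate early genes had 12 of 18 up and 0 down (13 up adjusted over the list alone, list adjusted p = 1.45e-14, and 0.0432 with an estimated correlation). Among them were Nr4a3 (11.7-fold) and Fosb (8.99-fold, from a mean of 1.96 at room temperature, below the array medians).

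Falls in the cold in the arrays labelled knockout included Irs3 (6.75-fold), Hcar1 (6.58-fold), Tspan18 (5.89-fold), Cish, an inhibitor of cytokine signalling (5.42-fold), the glycogen regulator Ppp1r3b (5.4-fold), Gbp4 (4.86-fold), Per3 (4.68-fold) and Srebf1 (4.6-fold). Rises included Prg4 (15.2-fold), the clock factor Npas2 (13.4-fold), Fabp9 (11.2-fold), Maff (8.32-fold), Acot5 (8.04-fold) and Drd1 (7.51-fold). The lower group averaged 1.91 for Npas2, 1.96 for Fabp9, 2.21 for Maff, 2.81 for Acot5, 1.89 for Drd1, 2.32 for Irs3, 2.59 for Hcar1 and 1.93 for Gbp4, near or below the array medians, so these folds are lower estimates if the readings are background. Lipogenesis had 6 of 19 down and 0 up (8 down adjusted over the list alone), with Mlxipl (-1.11 ± 0.13) and Acacb (-0.93 ± 0.12) beside Srebf1, at a list adjusted p of 9.05e-07 (adjusted p = 0.376 with an estimated correlation). Adipocyte identity had 4 of 13 down and 0 up (7 down adjusted over the list alone), led by Cebpa (-1.67 ± 0.18), at a list adjusted p of 0.00011 (0.0432 with an estimated correlation). Interferon-stimulated genes had 4 of 17 down and 0 up (9 down adjusted over the list alone), with a median of -0.70 and a list adjusted p of 1.58e-06 (adjusted p = 0.509 with an estimated correlation). Of these, Ddx58 (-1.16 ± 0.24) kept its call with each array left out, and Ifih1, Stat2 and Irf7 did not (adjusted p up to 0.143, 0.127 and 0.155). Oxidative stress genes had 5 of 14 up and 0 down (7 up and 1 down adjusted over the list alone), with Srxn1 (1.13 ± 0.12) and Gclc (1.08 ± 0.13) as examples, at a list adjusted p of 0.000543 (adjusted p = 0.21 with an estimated correlation). The muscle markers were not called here, with 0 of 19 past the test, a median of 0.68 and a list adjusted p of 0.216.

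In total 2123 probe sets were called for cold in the arrays labelled knockout, 1017 higher and 1106 lower, and 604 by at least 2-fold. The count was 1396 without knockout replicate 2 at room temperature, and 1378 and 1276 without knockout replicates 1 and 2 at 4 °C. It was 2028 without the array with the conflicting label, and 1044 with that array among the 4 °C controls. In that last fit Ppargc1a, Dio2, Fosb and Cebpa were not called (adjusted p = 0.159, 0.0856, 0.052 and 0.137). The cold responses of both genotypes, whose group means share no array, had 545 probe sets up in both and 589 down in both. Between independent lists, 49.3 and 68.9 would overlap by chance, but these calls share 1 estimate of the spread. Another 9 changed in opposite directions, and r was 0.636 across all probe sets. When only the arrays compared were fitted, with no shared spread, 414 rose and 457 fell in both. The 545 and 589 were 354 and 375 without knockout replicate 2 at 4 °C, and the 589 was 382 without knockout replicate 2 at room temperature. Both were 0 with the array with the conflicting label among the 4 °C controls, where limma called 0 probe sets for cold in the controls (3602 at an unadjusted p under 0.05). Averaged over genotypes, 4139 probe sets were called for cold, 1767 higher and 2372 lower (3865 without the array with the conflicting label and 2267 with it among the 4 °C controls). In that average 19 of 23 genes of the integrated stress response rose and 0 fell (19 up and 1 down adjusted over the list alone, list adjusted p = 4.3e-16, and 0.000584 with an estimated correlation).

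**Figure D3:**
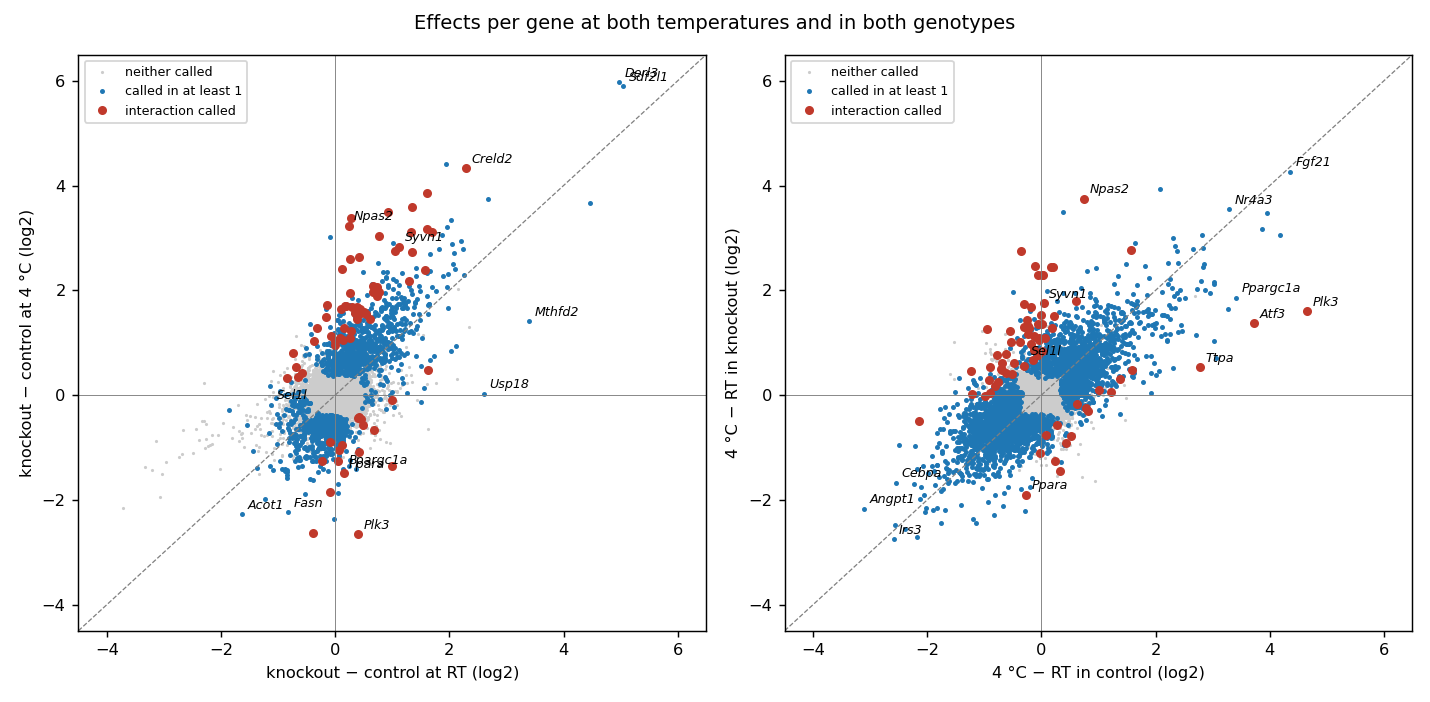
Log2 differences per probe set. Left, the genotype effect at room temperature (x axis) against that at 4 °C (y axis), and right, the cold effect in controls (x axis) against that in the arrays labelled knockout (y axis), with grey points called in neither, blue in at least 1 comparison, red by the interaction test, and the dashed line marking equal effects (r = 0.496 and 0.636 across all probe sets).

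The cold response differed between genotypes for ER quality control genes, again with the 4 °C label unchecked by Sel1l. Of the 19 genes of ER chaperones and folding, 6 had a higher and 0 a lower response in the arrays labelled knockout (17 higher adjusted over the list alone), with a median interaction of 0.82 and a list adjusted p of 4.8e-22 (0.042 with an estimated correlation). Of 20 ERAD genes, 3 had a higher and 0 a lower response (8 higher adjusted over the list alone), with a median of 0.42 and a list adjusted p of 5e-08 (0.042 with an estimated correlation). Herpud1 (1.51 ± 0.21, adjusted p = 0.0116), Syvn1 (1.71 ± 0.32, 0.0492), Os9 (0.92 ± 0.15, 0.0294), Dnajb11 (1.42 ± 0.21, 0.0169) and Creld2 (2.05 ± 0.34, 0.0294) were among these. Each lost its call without at least 1 array (adjusted p up to 0.0534, 0.123, 0.099, 0.0744 and 0.099, all without knockout replicate 2 at 4 °C). Hspa5 (0.63 ± 0.19, adjusted p = 0.251) and Derl3 did not pass.

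The largest interactions upward were Prdm15 (3.11 ± 0.23, adjusted p = 0.000133), Npas2 (3.00 ± 0.28, 0.000515), Rbm15b (2.56 ± 0.41, 0.0265), Krt23 (2.34 ± 0.22, 0.000515) and the cytokine subunit Il23a (2.29 ± 0.17, 0.000133). The largest downward were Plk3 (-3.06 ± 0.28, adjusted p = 0.000515), Atf3 (-2.36 ± 0.40, 0.0314), Ttpa (-2.26 ± 0.38, 0.0311), Mavs (-1.76 ± 0.22, 0.00625) and Ppara (-1.64 ± 0.25, 0.0188). Atf5 also had a lower response (-1.16 ± 0.16, 0.00893). Prdm15, Npas2, Krt23 and Il23a averaged at most 2.98, 2.43, 1.85 and 1.83 in the groups other than the arrays labelled knockout at 4 °C, near or below the array medians, so that a cold response in the controls was not measurable where these readings are background. The same holds for Fkbp11 and Plscr2, at 2.27 and 2.72 in the 4 °C controls, and Ttpa averaged 2.51 in the arrays labelled knockout at room temperature. Of the 20 named genes called here, 7 kept the call with each array left out, namely Prdm15, Npas2, Krt23, Il23a, Plk3, Mavs and Atf5. Of these, Plk3 and Atf5 were not called with the array with the conflicting label among the 4 °C controls (adjusted p = 0.781 and 0.721). Rbm15b, Atf3, Ttpa and Ppara did not (adjusted p up to 0.0845, 0.101, 0.099 and 0.0793, all without knockout replicate 2 at 4 °C).

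Among lists, the thermogenic program (median -0.38, 1 of 20 lower, 4 lower adjusted over the list alone) and lipogenesis (median -0.52, 1 of 19 lower, 2 adjusted over the list alone) had lower cold responses, with list adjusted p-values of 0.000396 and 3.36e-05. So did glycolysis (median -0.12, 0 of 16 called, 1 lower adjusted over the list alone) and interferon-stimulated genes (median -0.93, 0 of 17 called, also adjusted over the list alone), with 0.0403 and 3.44e-08. With an estimated correlation none of these 4 passed (adjusted p = 0.516, 0.608, 0.899 and 0.603), and the glycolysis call was also lost when any of 6 single arrays was left out (list adjusted p up to 0.233, without knockout replicate 1 at 4 °C). The muscle markers had a median interaction of 1.43, with 0 of 19 called and a list adjusted p of 0.0136 (adjusted p = 0.899 with an estimated correlation). This call was lost when any of 7 single arrays was left out (list adjusted p up to 0.537, without knockout replicate 2 at 4 °C). In total 72 probe sets were called for the interaction, 54 upward and 18 downward. The count was 29, 26 and 38 without control replicates 1, 2 and 3 at room temperature, and 33, 36 and 123 without control replicates 1, 2 and 3 at 4 °C. It was 34 and 46 without knockout replicates 1 and 3 at room temperature, and 45, 21 and 36 without knockout replicates 1, 2 and 3 at 4 °C. It was 22 over all probe sets with or without a symbol, 17 with the array with the conflicting label among the 4 °C controls, and 40 with the muscle score as a covariate.

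Several lists were called in none of the 4 comparisons of 2 groups. Their smallest list adjusted p was 0.109 for ER-mitochondria contacts, 0.187 for fission and fusion, 0.418 for mitochondrial chaperones and proteases, 0.187 for lipolysis and lipid uptake, 0.187 for extracellular matrix, 0.546 for the cell cycle and 0.39 for white adipocyte markers. For other cell types it was 0.108 for macrophages, 0.214 for T and B cells, 0.205 for fibroblasts and preadipocytes, 0.851 for Schwann cells and nerve, 0.323 for red blood cells, of which 2 markers were measured, and 0.687 for sex-linked genes. No list called in a comparison had a median, mean and test of different sign. Among the lists not called, signs differed in several, mostly with values near 0. For example, ER-mitochondria contacts had a median of -0.02 with a mean of 0.17 and an upward test for genotype at room temperature. Macrophage markers had a median of -0.01 with a mean of 0.10 and an upward test for cold in the arrays labelled knockout.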

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

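The tests of mislabelled samples, of other cell types and of probes outside the deleted part, the muscle covariate, the array with the conflicting label, the tests of muscle carry-over and of a genotype effect on muscle, and the splits of deviations were chosen only after the result was seen.

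A difference between the cold responses of the genotypes, by the interaction test, was called for 72 probe sets. Among ER quality control genes it was 2.05 for Creld2, 0.82 for Pdia3, 1.71 for Syvn1, 0.92 for Os9, 2.25 for Fkbp11, 1.51 for Herpud1, 1.42 for Dnajb11, 1.78 for Ero1b and 0.87 for P4hb on the log2 scale. Among other genes it was 3.11 for Prdm15, 3.00 for Npas2, 2.56 for Rbm15b, 2.34 for Krt23, 2.29 for Il23a, 2.26 for Plscr2, 1.65 for Cd274 and 1.13 for Gclc upward. Downward it was -3.06 for Plk3, -2.36 for Atf3, -2.26 for Ttpa, -1.76 for Mavs, -1.64 for Ppara, -1.16 for Atf5 and -1.11 for Gpam. The controls read near or below the array medians for Fkbp11, Prdm15, Npas2, Krt23, Il23a and Plscr2, so the sizes of these interactions are not exact. Lists picked out by the same test had median interactions of 0.82 for ER chaperones and folding, 0.42 for ERAD, -0.38 for the thermogenic program, -0.52 for lipogenesis, -0.12 for glycolysis, -0.93 for interferon-stimulated genes and 1.43 for skeletal muscle markers. Only the ER chaperone and ERAD lists held with an estimated correlation (adjusted p = 0.042 each), and the other 5 did not (0.516, 0.608, 0.899, 0.603 and 0.899). A signal in data that no comparison of named genes used was seen in the probe sets without a single gene symbol, of which 172 of 17824 were higher and 41 lower in the arrays labelled knockout at 4 °C. These 213 calls are a smaller share than the 1365 of 23521 among probe sets with 1 symbol. Of the 17824, 1814 carried several symbols.

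The Sel1l reading was not called lower in the arrays labelled knockout at 4 °C. Control mice in place of knockout mice were argued against by the ER chaperone list, which lay 2.71 higher in these arrays than in the controls at 4 °C and at least 2.58 higher with each array left out. More RNA from other cells that keep Sel1l was argued against for 6 lists of immune, fibroblast, nerve and red blood cell markers, of which the highest median change in the cold was 0.002 and the largest SD over markers 0.48, beside the rise of Sel1l of 0.66. Skeletal muscle markers, with 0 of 19 called, differed as far, by a median of 0.68 with 17 of 19 positive, but the rise of Sel1l was 0.656 with the muscle score as a covariate (adjusted p = 0.0195), which argues against muscle RNA as its whole cause; endothelial RNA stays open (median 0.268, SD 0.74). Probes outside the deleted part may account for that rise of 0.66 ± 0.14, if they read a locus that rises in the cold. In the controls, Sel1l read 7.37, 6.96 and 7.23 at room temperature and 6.99, 6.69 and 7.04 at 4 °C. These values argue against a locus that rises in the cold in both genotypes. A locus that rises only in the arrays labelled knockout stays open, since that rise was the observation itself and probe positions were not used here.

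The ER chaperone list rose more in the cold in the arrays labelled knockout, by a median of 0.82. Muscle RNA as the whole cause was argued against by a median of 0.80 with the muscle score as a covariate (list adjusted p = 7.9e-21), and normalization between arrays by 0.83 after cyclic loess (5.7e-23). The array with the conflicting label was argued against by 0.84 without it (2.48e-19). A larger demand on ER folding in the cold without Sel1L may underlie this, as a hypothesis for which no test was run, and the call itself stood at an adjusted p of 0.042 with an estimated correlation.

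Skeletal muscle markers spread widely between arrays. Muscle RNA carried over at dissection had the values it needs, since within groups each of the 19 markers followed the mean of the others, with a lowest correlation of 0.871 over 12 arrays. A lowering of muscle transcripts by the deletion of Sel1L stays open, since the difference of -1.77 had an exact two-sided permutation p of 0.09 and an interval reaching down to -3.81.

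Other splits of the same arrays were also tested. For each comparison of 2 groups, the 10 splits of 6 arrays are too few for a share under 0.05; the real split, the 1 split with as many calls, gave 404, 1365, 2606 and 2123 probe sets for genotype at room temperature and 4 °C and for cold in the controls and the arrays labelled knockout, and the highest other split gave 0 in each. For the average genotype effect (1638 probe sets, 430 in the highest other split) and the average cold effect (4139, 354 in the highest other), only the real split reached the count. This share of 1 in 100 is the smallest that 100 splits can give. It concerns the count of calls, not any 1 gene or list. For the interaction, 6 of 100 splits, the real one included, gave at least the real 72. The others gave 214, 260, 379, 1638 and 275, and each kept all or none of the knockout labels at 4 °C. Such splits carry the genotype effect into the interaction, so this test could neither exclude chance nor show that chance reaches 72. The highest split, with 1638, exchanged the genotypes at 4 °C and so by construction measured the average genotype effect. With the average effects removed first, 1 of 100 splits of the deviations, the real one, gave 72, and the highest other gave 0. The effects removed were those of the real labels. This leaves the real interaction whole and takes away part of the interaction of other splits. The test therefore favours the real split and cannot exclude chance either.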

How the results depend on the processing

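The muscle score as a covariate was chosen after the data had been seen. Of 151 alternative values of the 7 counts, 119 lay within 1.5 times the reported count, 31 were lower and 1 was higher. Of 2400 alternatives of 150 list results, 2291 kept direction and side of the threshold, as did 9408 of 10233 alternatives of 469 results of named genes; for the others not named here, the cause was not tested.

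The count for genotype at room temperature, 404, was 245 with only the arrays compared, 177 with the array with the conflicting label among the 4 °C controls, and 188 with the muscle covariate. That relabelling, against which the readings of the array argue, gave 0 for cold in the controls (2606 as titled), where 3602 had an unadjusted p under 0.05 in limma. It gave 1044 for cold in the arrays labelled knockout (2123), 17 for the interaction (72) and 2267 for the average cold effect (4139). The interaction count was also 22 over all probe sets, where more were tested, 47 with a replicate block and 40 with the muscle covariate, which lowered the average genotype count from 1638 to 1010. Apart from the wider testing, the cause was not tested. With each array left out, counts were 255 to 458 and 842 to 1345 for genotype at room temperature and 4 °C, 1608 to 2875 and 1276 to 2300 for cold in the controls and the arrays labelled knockout, and 21 to 123 for the interaction, with fewer arrays in each fit.

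Directions reversed for Nr4a3 by genotype at 4 °C, at 0.097 with the relabelled array (-0.69 as titled), and the direction of the list test for the muscle markers. Their median was 0.061, -0.01 (the same sign as -1.07, with the test reversed) and -0.037 for genotype at room temperature, genotype at 4 °C and the interaction with the muscle covariate, which is built from them, and for genotype at 4 °C it ranged from -1.81 to 0.141 with each array left out, the last without knockout replicate 1 at 4 °C.

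With the replicate number as a block the counts were 362, 1232, 2413, 1948 and 47 for the pairwise comparisons and the interaction and 1553 and 4040 for the averages, and 21 calls of named genes and 3 of lists were lost. Deviations of arrays with the same number correlated by -0.014 to 0.113 and -0.162 to 0.165 for genotype at room temperature and 4 °C, and by -0.079 to 0.023 and -0.18 to -0.027 for cold in the controls and the arrays labelled knockout, and 1, 1, 0 and 0 of 3 pairs were best matched by number, so the numbers were not taken to pair the samples. Signal near the background or near the top of the scale limits what these arrays can show, as for Ucp1.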

Other observations

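Clock genes of the arrays labelled knockout moved in both directions in the cold, with 6 of 15 up and 4 down (6 and 5 adjusted over the list alone). Their list adjusted p of 0.422 is from a test for a shared direction, so it does not speak against such a change. Arntl, the partner of CLOCK, rose 7.15-fold (2.84 ± 0.41, n = 3 per group, adjusted p = 0.00105), and Tef fell by 0.91 on the log2 scale (SE 0.16). Endothelial markers had 3 of 14 up and 3 down in the same arrays (3 and 5 adjusted over the list alone, list adjusted p = 0.509), with Sox17 (1.94 ± 0.23), Robo4 (0.88 ± 0.13) and Esam (0.73 ± 0.15) up and Emcn down (-0.73 ± 0.15, not called with the array with the conflicting label among the 4 °C controls, adjusted p = 0.184). Of 17 macrophage markers, 3 rose in the cold in each genotype and 0 fell (4 up in each adjusted over the list alone). Cd14, a receptor for bacterial lipopolysaccharide, rose by 0.71 ± 0.14 in the controls (adjusted p = 0.00568) and by 0.98 ± 0.14 in the arrays labelled knockout (0.00101), while the list was not called (list adjusted p = 0.108 and 0.318).

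Genes of ER-mitochondria contacts had 3 of 24 up and 1 down in the cold in the controls, and 3 up and 3 down in the arrays labelled knockout (4 and 1, and 4 and 3, adjusted over the list alone), with list adjusted p-values of 0.836 and 0.629. Acsl4, which activates arachidonic acid, rose in both (0.70 ± 0.13 and 0.87 ± 0.13), and Ptdss2 fell in the arrays labelled knockout (-0.87 ± 0.14), with an interaction of -0.86 ± 0.20 that did not pass (adjusted p = 0.104). The Y-linked gene Eif2s3y read 7.28 to 8.12 and Xist 1.08 to 1.39 in all 12 arrays.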
